A study of Mus musculus with 12 samples.

How the data were processed

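Primary hippocampal neurons from newborn mice were kept in culture for 16 days, and RNA from a pulldown directed at Gas5, a long noncoding RNA that hosts small nucleolar RNAs (snoRNAs) in its introns, was sequenced as total RNA and as small RNA. The titles place the 12 libraries in 4 groups of 3: antisense and sense for total RNA, and antisense and sense for small RNA. The labels do not say which of antisense and sense was the capture and which the control, nor whether the words refer to a probe or to a bait, so the groups keep those names. They also do not say whether the 3 libraries of a group came from separate cultures, and p-values then measure only the spread between these libraries, which may be technical.

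Salmon, DESeq and the genome build GRCm38 are named in the submitters' processing notes, with no versions. The aligner settings, the transcript index, the kit and whether counting used strand are not given in the sources used here. Reads of a gene and of a partner on the other strand may therefore not be told apart, and genes that overlap others or have near-identical copies are uncertain. The total RNA table deposited by the authors holds estimated counts for 49489 gene symbols, and the small RNA table deposited by the authors holds estimated counts for 137960 rows, of which 1964 name miRNAs and 135996 are transcript identifiers. The authors' deposited comparison tables give a mean normalised signal, a log2 fold change with its standard error, a p-value and an adjusted p-value per row. They hold no library values and served only for a side-by-side reading. No column of sample values was left unused.

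Estimated counts were rounded to whole numbers. Rows were kept by filterByExpr with a minimum count of 10, TMM factors were computed on the kept rows, and edgeR's quasi-likelihood F test, two-sided, compared antisense minus sense within each assay with no further term. Adjusted p-values are Benjamini-Hochberg values at a false discovery rate of 0.05. For small RNA the test ran on rows naming miRNAs, with totals over those rows. CPM values are counts scaled by the TMM-effective library size with edgeR, and the standard error of a log2 fold change was taken as its size over the square root of F. Where all 3 libraries of a group were at 0, the fold was set against a floor of 3 counts over the group and is given as a lower bound. Intervals of shares are exact Clopper-Pearson intervals at 95%. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

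Lists of genes (21 for total RNA) and miRNAs (9 for small RNA) were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists with 3 or more tested members were tested with limma's camera on voom values with an inter-gene correlation of 0.01, and again with an estimated correlation. A miRNA row belonged to a list when its name, without arm and copy number, matched a member. The text names Gas5, then, per assay and direction, the 10 rows with the largest log2 fold change among those passing whose 3 libraries of one group all lay beyond the other 3. Where fewer than 5 rows passed in a direction, the 5 with the smallest p are named as not passing. From each list up to 3 members are named, by smallest p in total RNA and by highest mean CPM in small RNA. A few genes that the rule picks are not reported here by name, for reasons unrelated to their values, and stay in the counts of the lists. Camk2b, Hif3a, Nr3c1, mt-Nd1, Dcp2, Puf60, mt-Tc, mt-Ty, mt-Tl2 and miR-375-5p fall outside the rule and were chosen after their values were seen. Ratios of genes with 1 to 3 counts over a group are given with an exact 95% interval conditional on the sum of both counts.

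Gene positions came from a RefSeq table of assembly GRCm38.p6, matched by symbol for 37788 of 49489 genes and for 37892 once synonyms were used. A gene was classed as overlapping an expressed gene when another gene of the table overlapped its span and reached a mean of 10 CPM. That mean was taken over antisense and sense libraries together, so antisense counts alone could make a partner expressed. This was so for Npas3, whose partner 1700030L22Rik, at a mean of 18.1 CPM, had 0 counts in sense. The table gives no strand, and these classes were defined after the data were seen.

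Total RNA libraries held 5775052 to 10424167 counts and small RNA libraries 3527528 to 4448328, of which 193501 to 258237 were in miRNA rows. The steps were tested on simulated counts drawn with the real mean of each gene over all libraries and with TMM-scaled depths. In total RNA 200 genes were changed, in both directions, and the real difference of Gas5 between groups was not built in. The rates therefore do not cover data in which 80.7% of the calls go in 1 direction. In total RNA, 24 of 64 genes changed 1.5-fold (37.5%), 50 of 65 changed 2-fold (76.9%) and 61 of 64 changed 4-fold (95.3%) were recovered. There were 12 false calls among 19303 genes, to be read against these recovered genes rather than against all genes. In small RNA, 2 of 7 miRNAs changed 1.5-fold (28.6%), 4 of 6 changed 2-fold (66.7%) and 6 of 6 changed 4-fold (100%) were recovered. There was 1 false call among 153 miRNAs, and rates from so few changed miRNAs are rough. No pair of libraries was alike within sampling noise: the smallest chi-square per degree of freedom over all pairs was 4.26.

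The alternatives were median-of-ratios factors, library totals with no further factor, DESeq2, limma-voom with quality weights, no filter, a minimum count of 50, the replicate number as a block, each library left out in turn, all rows of the small RNA table, and an estimated inter-gene correlation. Gas5 left out of the totals and a test on genes that overlap no other gene were added after the data were seen. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, GenomicRanges 1.54.1 and matplotlib 3.10.9.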

Results

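The series compared libraries called antisense and sense from a pulldown of Gas5 in cultured mouse hippocampal neurons at day 16 in vitro, asking which long and small RNAs differed between them. Each assay had 3 antisense and 3 sense libraries. Total RNA libraries held 5813061, 6293093 and 5775052 counts in the antisense group and 10424167, 6478779 and 7594951 in the sense group. In total RNA, 35305 of 49489 genes had a count above 0 and 20049 were tested. Small RNA libraries held 3527528 to 4448328 counts, of which 5.197% to 6.455% lay in miRNA rows, and 158 of the 1964 miRNAs were tested.

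Gas5, the RNA the pulldown was aimed at, was the most abundant RNA of every total RNA library and was lower in the antisense group. It took 9.71% (95% exact interval 9.68% to 9.73%), 14.2% (14.17% to 14.23%) and 10.84% (10.82% to 10.87%) of the antisense counts and 57.13% (57.10% to 57.16%), 32.66% (32.63% to 32.70%) and 46.12% (46.08% to 46.15%) of the sense counts. The group means were 11.6% ± 2.34 and 45.3% ± 12.3 (SD, n = 3 each), so the mean share was 3.91 times as high in the sense libraries, and all 3 lay above all 3 antisense libraries. Scaled by TMM, Gas5 stood at 90938 ± 21187 CPM in antisense and 623730 ± 306610 CPM in sense, a log2 fold change of -2.78 (SE 0.286; edgeR adjusted p = 3.76e-06). On library totals alone the log2 fold change of Gas5 in total RNA was -1.96. The gene lies on chromosome 1 from 161034601 to 161038539 (GRCm38.p6), where Zbtb37 overlaps it. Of the 10 snoRNAs hosted by its introns that were listed beforehand, 3 had a row in the total RNA table and none was tested. In the small RNA table no row carries one of their names.

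**Figure D1:**
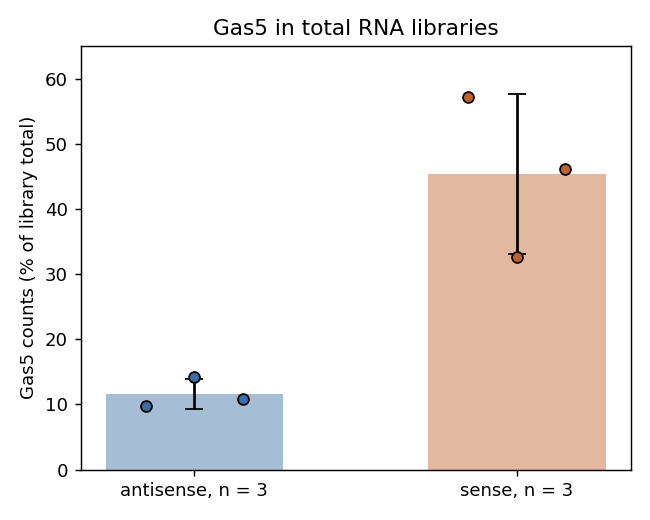
Gas5 counts as a percent of the total count of each total RNA library (y axis) for the antisense and sense groups (x axis). Bars are means of 3 libraries, error bars are 1 SD and points are libraries; the 3 antisense points lie between 9.71% and 14.2% and the 3 sense points between 32.66% and 57.13%.

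Outside Gas5, far more genes were higher than lower in the antisense libraries. Of 20049 genes tested, 3658 were higher and 873 lower (edgeR quasi-likelihood test, Benjamini-Hochberg), so 80.7% of the calls were higher. More than 4-fold, 1776 genes were higher and 25 lower, and 624 of the higher genes had no count in any sense library. Libraries of the groups did not overlap for 36.6% of genes, against 10% by chance. Long noncoding RNAs and processed pseudogenes were prominent: 1620 of 3549 long noncoding RNA genes (45.6%) and 462 of 949 processed pseudogenes (48.7%) were higher, against 1452 of 15030 protein-coding genes (9.66%). Genes overlapping an expressed gene were higher in 1120 of 3164 cases (35.4%), genes overlapping only genes of low count in 355 of 3953 (8.98%), and genes overlapping no other gene in 1054 of 10494. Of 2438 tested genes without a position in the table used, 1129 were higher (46.3%). TMM left the median log2 fold change of all genes at -0.01. Library totals alone moved it to 0.70 and gave 12804 higher and 62 lower genes (99.5% higher), so each direction here is relative to the TMM scale. Library totals include Gas5, whose larger share in sense lowers the shares of all other genes there.

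The genes that stood highest against the sense libraries were at 0 there and at 16.7 to 36.3 CPM in antisense. The noncoding gene 1700030L22Rik, on chromosome 12 from 53298724 to 53317139 within the span of the expressed transcription factor gene Npas3, reached 36.3 ± 1.01 CPM (SD, n = 3), at least 225-fold higher (edgeR adjusted p = 1.81e-09). Next came 4933400F21Rik, which overlaps Agap1, at least 176-fold higher, 1700109K24Rik, which overlaps Rbfox2, at least 123-fold, and Gm9831, which overlaps the microtubule-associated kinase gene Dclk1, at least 121-fold. The pseudogene Gm15916, which overlaps Ube2e2, was at least 111-fold higher. B230217J21Rik (at least 118-fold), 4930570B17Rik (at least 107-fold), Plxna4os2 (at least 107-fold) and Gm26743 (at least 105-fold), all noncoding, had no position in the table used. The only protein-coding gene of the 10 was Myh6, a cardiac myosin heavy chain, at 16.7 ± 3.05 CPM and at least 104-fold higher. Myh6 overlaps Cmtm5, which at a mean of 9.9 CPM lay just under the 10 CPM set for an expressed gene. Since counting by strand is not stated, the values of overlapping genes are uncertain.

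**Figure D2:**
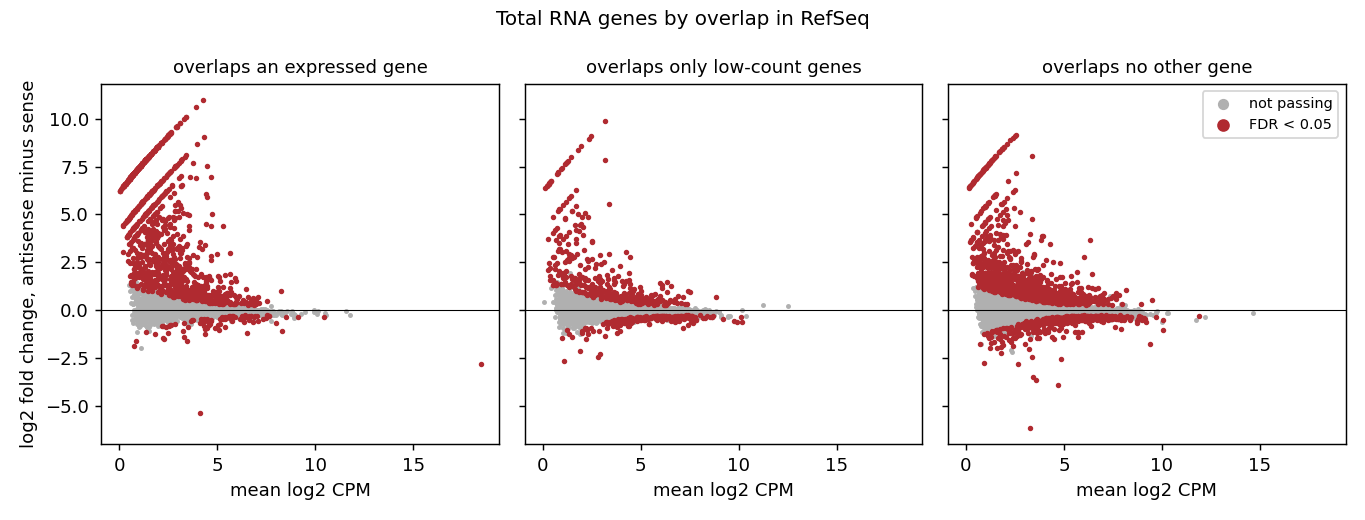
Log2 fold change, antisense minus sense (y axis), against mean log2 CPM (x axis) for tested total RNA genes, in panels for genes overlapping an expressed gene, only genes of low count, or no other gene. Each point is a gene and red points pass an edgeR adjusted p of 0.05; 735 of 3164 genes in the first panel and 278 of 10494 in the last were over 4-fold higher, 2438 tested genes without a position (652 over 4-fold higher, 26.7%) are in no panel, and diagonal rows of points are genes with few or no sense counts.

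Genes with the largest decreases in antisense were mostly noncoding RNAs and pseudogenes. Gm47106, a long noncoding RNA, stood at 8.89 ± 1.71 CPM in antisense and 334 ± 17.7 CPM in sense (SD, n = 3), a 37.5-fold difference with the smallest edgeR adjusted p of all genes, 8.94e-12. Gm13056, a noncoding gene on chromosome 4 overlapping no other gene, had a log2 fold change of -6.13 (SE 0.482), and Pcdhga10, a clustered protocadherin that shares its last exons with other genes of its cluster, one of -5.34 (SE 0.404). Olfr769, an odorant receptor gene on chromosome 10 from 129111485 to 129112423, fell to 3.24 ± 0.868 CPM from 48.9 ± 10.47 CPM (SD, n = 3), and its family has many similar copies. Log2 fold changes were -3.81 for Gm49057, -3.62 for Gm35419, -3.49 for Gm8489 and -2.96 for AC122537.1. Gm50401 had 65 counts in sense and 2 in antisense, a scaled ratio of 40.0 (95% exact interval 10.6 to 337), and Gm11991 had 77 and 3, a ratio of 31.6 (10.4 to 156). Leaving out 1 library kept each of these 10 and the 10 highest genes past the threshold. The number of lower genes did depend on single libraries, with 571 without antisense replicate 1, 534 without sense replicate 1 and 492 without sense replicate 3.

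Neuronal mRNAs leaned lower in the antisense libraries on the TMM scale, by small amounts. Of 23 presynaptic genes tested, 7 were lower, none was higher and 16 did not pass, with a median log2 fold change of -0.35 (camera adjusted p = 6.78e-05, and adjusted p = 0.541 with an estimated correlation; 7 lower adjusted over the list alone). Bsn, which encodes the active zone scaffold Bassoon, changed by -0.75 (SE 0.173) and the active zone gene Pclo by -0.47 (SE 0.126). Of 22 neuronal cytoskeleton genes, 8 were lower and 14 did not pass (median -0.34; camera adjusted p = 6.78e-05, and adjusted p = 0.541 with an estimated correlation; 11 lower adjusted over the list alone). Among the 8 were the microtubule-associated genes Map1a (-0.68, SE 0.137) and Map1b (-0.61, SE 0.154) and the kinesin Kif5a (-0.60, SE 0.156). Of 24 postsynaptic glutamatergic genes, 4 were lower and 20 did not pass (median -0.22; camera adjusted p = 6.78e-05, and adjusted p = 0.541 with an estimated correlation; 7 lower adjusted over the list alone). They were the kinase gene Camk2a (-0.51), the adhesion gene Nlgn3 (-0.34), the pentraxin gene Nptx1 (-0.50) and, chosen after its value was seen, Camk2b (-0.31). Of 16 GABAergic neuron genes, 2 were lower, among them Reln (-0.56), and 1 was higher, the interneuron homeobox gene Dlx1 (2.21, SE 0.261). That list had a median of -0.25 (camera adjusted p = 0.0418, and adjusted p = 0.577 with an estimated correlation; 1 higher and 1 lower adjusted over the list alone), and did not pass without antisense replicate 3 (adjusted p = 0.273) or sense replicate 1 (adjusted p = 0.123), nor at a minimum count of 50 (0.0916). Among genes overlapping no other gene the adjusted p was 0.0607 for the cytoskeleton list and 0.204 for the GABAergic list. Within the sense group, replicate 1 had the highest and replicate 2 the lowest CPM of Bsn, Pclo, Map1a, Map1b, Kif5a, Camk2a, Nlgn3, Nptx1 and Reln, as with the Gas5 share. Bsn stood at 283.8, 153.3 and 215.1 CPM in sense replicates 1, 2 and 3 and at 142.5, 138.3 and 107.0 in the antisense libraries. Without sense replicate 1 its log2 fold change was -0.52, and the camera adjusted p was 0.000963 for presynaptic, 0.00201 for cytoskeleton and 0.000441 for postsynaptic genes. Bsn, Map1a and Dlx1 passed whichever library was left out, and each other gene named here lost its call without at least 1 library. On library totals alone, which include Gas5, every lower gene named here had a positive log2 fold change.

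Lists of genes acting on RNA and translation, and of neuronal long noncoding RNAs, had slightly negative medians on the TMM scale. None lay below 95% of random lists of like abundance drawn from protein-coding genes overlapping no other gene. The random medians were -0.13 for RNA granule genes, -0.13 for translation factors, -0.09 for ribosomal protein genes and -0.15 for the noncoding RNAs. For the noncoding RNAs these random lists match abundance but not the kind of gene. Of 34 RNA granule and RISC genes, 5 were lower and 29 did not pass (median -0.15; camera adjusted p = 6.84e-05, and adjusted p = 0.467 with an estimated correlation; 4 lower adjusted over the list alone). Among the 5 were Drosha, which encodes the nuclear RNase that cuts primary miRNA transcripts (-0.38, SE 0.0936), the neuronal RNA-binding gene Elavl3 (-0.41) and, chosen after their values were seen, the decapping gene Dcp2 (-0.30) and the splicing factor gene Puf60 (-0.35). Among 29 translation factors, Eif4g1 was lower (-0.42), Eif5b was higher (0.35) and the elongation factor gene Eef2 did not pass (-0.44). Their median was -0.13 (camera adjusted p = 0.00944, and adjusted p = 0.577 with an estimated correlation; 0 adjusted over the list alone). Among 78 cytosolic ribosomal protein genes, Rps18 (-0.37) and Rpl13 (-0.35) were lower, Rpl29 was higher (0.80) and 75 did not pass, with a median of -0.11 (camera adjusted p = 0.01, and adjusted p = 0.577 with an estimated correlation; 0 adjusted over the list alone). Among 18 abundant neuronal long noncoding RNAs, Tug1 (-0.36, SE 0.0862) and Miat (-0.25) were lower and Oip5os1 did not pass (-0.32). Their median was -0.12 (camera adjusted p = 0.0418, and adjusted p = 0.467 with an estimated correlation; 1 lower adjusted over the list alone). Without antisense replicate 3 the adjusted p was 0.119 for translation factors and 0.0984 for ribosomal protein genes and for the noncoding RNAs, which also missed the threshold without sense replicate 2 (0.0605) or sense replicate 3 (0.0506) and with Gas5 left out of the totals (0.0554). At a minimum count of 50 the adjusted p was 0.0697 for translation factors, 0.0916 for ribosomal protein genes and 0.133 for the noncoding RNAs, and among genes overlapping no other gene it was 0.0712, 0.204 and 0.0648. Drosha, Rpl29 and Tug1 passed whichever library was left out, and each other passing gene named here lost its call without at least 1. On library totals alone, which include Gas5, every lower gene named here had a positive log2 fold change. Eef2 passed as lower without antisense replicate 2 (adjusted p = 0.0344) or sense replicate 2 (0.00798), and Oip5os1 without antisense replicate 2 (0.0458) or sense replicate 2 (0.0392).

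Astrocyte, vascular, glucocorticoid-responsive and activity-regulated lists had negative medians on the TMM scale, and most of their members did not pass. Of 15 astrocyte markers, Atp1b2 (-0.49, SE 0.118) and Aldh1l1 (-0.46) were lower and the bicarbonate transporter gene Slc4a4 did not pass (-0.29). Their median was -0.28 (camera adjusted p = 0.00199, and adjusted p = 0.541 with an estimated correlation; 2 lower adjusted over the list alone). Of 13 vascular and fibroblast markers, the matrix genes Fn1 (-0.33) and Col4a1 (-0.33) were lower and the endothelial cadherin gene Cdh5 did not pass (-1.07, SE 0.39). Their median was -0.28 (camera adjusted p = 0.0136, and adjusted p = 0.541 with an estimated correlation; 0 adjusted over the list alone). Of 17 glucocorticoid-responsive genes, the metallothionein genes Mt1 (-0.41) and Mt2 (-0.49) and the clock gene Per1 (-0.34) were lower. Chosen after their values were seen, Nr3c1 (-0.29), which encodes the glucocorticoid receptor, was also lower and Hif3a was higher (1.15). The median was -0.24 (camera adjusted p = 0.0289, and adjusted p = 0.467 with an estimated correlation; 1 higher and 5 lower adjusted over the list alone). Of 21 activity-regulated genes, Jund (-0.57) and Nr4a1 (-0.86) were lower and Nr4a3 did not pass (-0.35). Their median was -0.15 (camera adjusted p = 0.0418, and adjusted p = 0.467 with an estimated correlation; 0 adjusted over the list alone), and the list did not pass without antisense replicate 3 (adjusted p = 0.076). At a minimum count of 50 the adjusted p was 0.0855 for glucocorticoid-responsive and 0.154 for activity-regulated genes. Among genes overlapping no other gene it was 0.0648 for astrocyte markers, 0.0712 for glucocorticoid-responsive genes and 0.131 for vascular markers and for activity-regulated genes. Of the passing genes named here Atp1b2 passed whichever library was left out and each other lost its call without at least 1, while Slc4a4 passed without sense replicate 2 (adjusted p = 0.0497). On library totals alone, which include Gas5, the lower genes named here had positive log2 fold changes, except Nr4a1. Within the sense group, Atp1b2, Slc4a4, Fn1, Cdh5, Mt1 and Mt2 had their highest CPM in replicate 1 and lowest in replicate 2. That order, given above for neuronal genes, did not hold for Aldh1l1, Col4a1, Per1, Jund, Nr4a1 and Nr4a3. Of the 71 named genes besides Gas5 that passed in total RNA, 34 lost the call without at least 1 library, most often without sense replicate 1 (27 genes) or sense replicate 3 (26 genes). Without antisense replicate 3, 7 lists passed in place of 12.

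**Figure D3:**
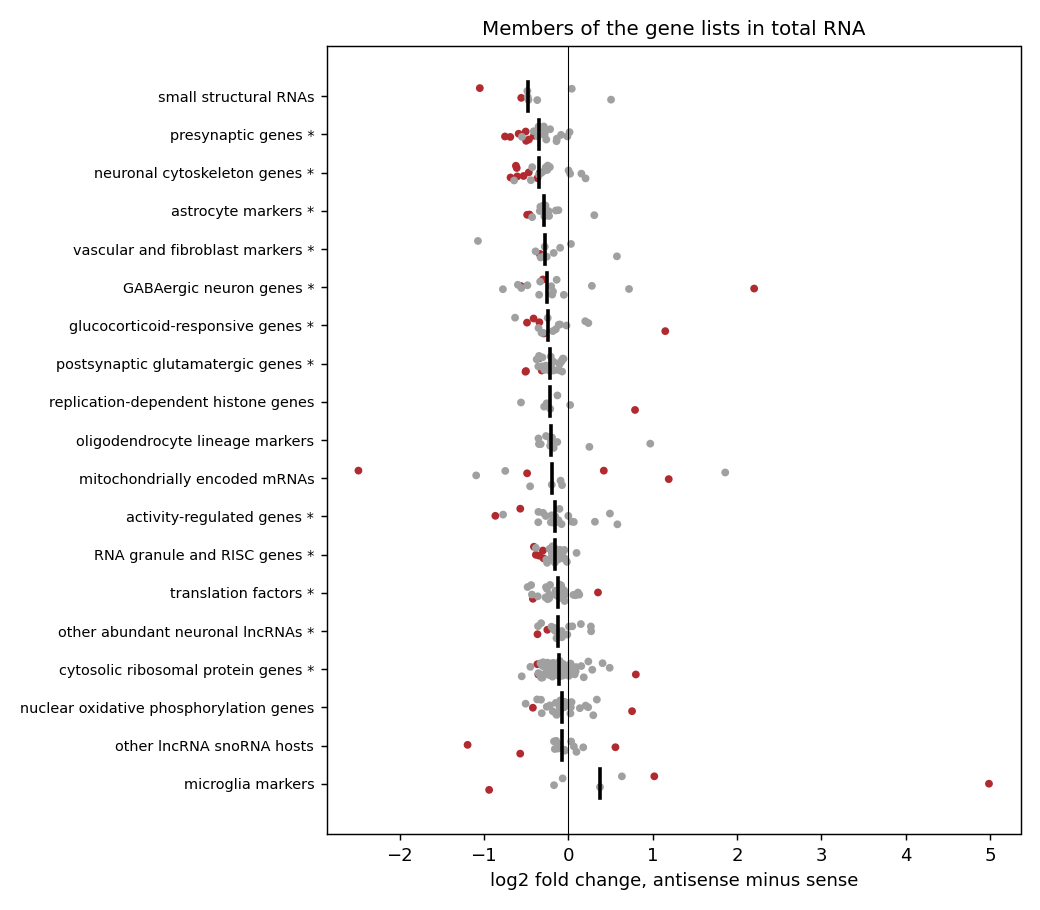
Log2 fold change, antisense minus sense (x axis), of tested members of the gene lists in total RNA (y axis), with the list median as a black bar. Red points pass an edgeR adjusted p of 0.05 and an asterisk marks a list with a camera adjusted p under 0.05; the medians of the 12 marked lists lie between -0.35 and -0.11.

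The remaining lists did not pass. Microglia markers went both ways among 7 tested (median 0.38; camera adjusted p = 0.467; 2 higher and 1 lower adjusted over the list alone). P2ry12, a purinergic receptor gene within the span of the expressed gene Med12l, was higher, with 91 counts in antisense and 2 in sense, a scaled ratio of 37.0 (95% exact interval 9.95 to 310), Trem2 was higher (1.02) and Itgam lower (-0.94). The 1 erythroid gene tested, Alas2, which encodes the first enzyme of heme synthesis, was at 15.6 ± 0.775 CPM in antisense (SD, n = 3) and 0 in sense, at least 96.5-fold higher, and lies on chromosome X within the RefSeq span of Apex2. Of 13 oligodendrocyte lineage markers none passed in edgeR (median -0.21; camera adjusted p = 0.0572; 0 adjusted over the list alone), with Mbp at -0.35 and Cspg4 at -0.33. This list passed without antisense replicate 1 (adjusted p = 0.0466), antisense replicate 2 (0.0328) or sense replicate 2 (0.00788), with a replicate block (0.0415) and with Gas5 left out of the totals (0.0363), against an adjusted p = 0.541 with an estimated correlation over all libraries. Among 11 mitochondrially encoded mRNAs, mt-Nd6 (1.19) and mt-Nd5 (0.42) were higher and mt-Nd4l (-2.49) and, chosen after its value was seen, mt-Nd1 (-0.49) were lower (camera adjusted p = 0.233, and 0.0273 without antisense replicate 2, against an adjusted p = 0.624 with an estimated correlation over all libraries; 2 higher and 3 lower adjusted over the list alone). Among 31 nuclear genes of oxidative phosphorylation, Ndufb2 was higher (0.76), Cox4i1 lower (-0.42) and the ATP synthase gene Atp5b not passing (-0.37), with a camera adjusted p of 0.107 (1 higher adjusted over the list alone). That list passed without antisense replicate 1 (adjusted p = 0.0486), antisense replicate 2 (0.0229) or sense replicate 2 (0.0182), against an adjusted p = 0.605 with an estimated correlation over all libraries. Among 14 other snoRNA host genes, Snhg15 was higher (0.56) and Snhg3 (-1.19) and Snhg20 (-0.57) were lower (camera adjusted p = 0.232; 1 higher and 2 lower adjusted over the list alone). Among 8 small structural RNAs, Scarna2 (-1.05) and Rmrp (-0.56) were lower and the neuronal RNA Bc1 did not pass (0.51), with a camera adjusted p of 0.0684, and 0.00229 without sense replicate 2, against an adjusted p = 0.541 with an estimated correlation over all libraries (1 higher and 3 lower adjusted over the list alone). Of 7 histone genes H2bc21 was higher (0.79), and H4c9 (-0.21) and H2bc4 (-0.29) did not pass (camera adjusted p = 0.442; 0 adjusted over the list alone). On library totals alone, which include Gas5, mt-Nd1, Cox4i1, Snhg20 and Rmrp had positive log2 fold changes. P2ry12, Alas2, mt-Nd6, mt-Nd4l, Ndufb2, Snhg15, Snhg3 and Scarna2 passed whichever library was left out, and each other passing gene named here lost its call without at least 1. Mbp and Bc1 passed without sense replicate 2 (adjusted p = 0.0199 and 0.0404), and Atp5b without antisense replicate 2 (0.0283) or sense replicate 2 (0.0165).

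The authors' deposited table for total RNA is coded in the other direction, sense over antisense: across genes its log2 fold changes correlate at -0.997 with the values above. At an adjusted p of 0.05 it lists 609 positive and 3852 negative genes, and all 3594 genes called in both have opposite signs as coded. It gives Gas5 a log2 fold change of 2.78 (SE 0.454; adjusted p = 3.88e-08) in that coding.

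In small RNA no miRNA that passed the filter on low counts differed between antisense and sense at the false discovery rate used. Of 158 miRNAs tested, 0 passed in edgeR, where 18 had an unadjusted p under 0.05, 9 in each direction, and the smallest adjusted p was 0.28. DESeq2 and limma-voom also gave 0, with 13 and 19 miRNAs at an unadjusted p under 0.05. The smallest p-values among miRNAs with higher means in antisense belonged to miR-1247-5p (log2 fold change 0.91, SE 0.276), miR-6238 (0.53, SE 0.173), miR-128-3p (0.57, SE 0.189), miR-98-5p (0.47, SE 0.182) and miR-449a-5p (0.50, SE 0.204). Among those with lower means they belonged to miR-365-3p (-1.62, SE 0.42), miR-148a-3p (-0.77, SE 0.222), miR-138-5p (-2.61, SE 0.822), miR-328-3p (-1.09, SE 0.371) and miR-29a-3p (-0.46, SE 0.168). miR-138-5p rested on 9 counts over the antisense libraries, all in antisense replicate 2, and 66 over the sense libraries. miR-328-3p rested largely on sense replicate 1, without which its log2 fold change was -0.40. With no filter on low counts 5 of these 10 miRNAs passed in edgeR: miR-1247-5p as higher (adjusted p = 0.00148), and miR-328-3p (4.97e-06), miR-138-5p (0.00161), miR-365-3p (0.0113) and miR-148a-3p (0.0379) as lower, as did miR-375-5p (3.34e-18). Without sense replicate 1, miR-148a-3p (adjusted p = 0.0325) and miR-375-5p (adjusted p = 0.00186) passed as lower. miR-375-5p, chosen after its value was seen, had 0 counts in every antisense library and in sense replicate 1, and 54 and 82 in the other sense libraries. The authors' deposited miRNA table, also coded sense over antisense, lists 365 miRNAs, none with an adjusted p under 0.05, 14 with an unadjusted p under 0.05 and a smallest adjusted p of 0.375.

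No miRNA list passed either. The let-7 family had 10 tested members, 0 passing, and a median of 0.18 (camera adjusted p = 0.175, and adjusted p = 0.467 with an estimated correlation). Its member let-7c-5p was the most abundant miRNA, at 231580 ± 55545 CPM in antisense and 199280 ± 30583 CPM in sense (SD, n = 3), and let-7a-5p stood at 0.36 and let-7f-5p at 0.41 on the log2 scale. Without antisense replicate 3 this list passed at a camera adjusted p of 0.000132, and without sense replicate 1 at 0.0234. Neuron-enriched miRNAs had a median of 0.05 and a mean of -0.12 over 13 members (camera adjusted p = 0.768), with miR-9-5p at 0.17, miR-9-3p at 0.0082 and miR-125b-5p at -0.02. Among 5 glial miRNAs miR-27b-3p stood at -0.10 (camera adjusted p = 0.333). Among 28 miRNAs of the imprinted Dlk1-Dio3 cluster, miR-382-5p stood at 0.16, miR-379-5p at -0.09 and miR-487b-3p at -0.28 (camera adjusted p = 0.333). For 4 miRNAs of the miR-17/92 and related clusters the median was 0.04 and the mean -0.02 (camera adjusted p = 0.768), with miR-93-5p at 0.22, miR-25-3p at -0.13 and miR-20a-5p at 0.46. For 5 members of the miR-30 family the camera adjusted p was 0.778, with miR-30d-5p at 0.0070, miR-30c-5p at -0.01 and miR-30a-3p at 0.19. Of the 9 miRNAs listed as partners of GAS5 elsewhere, 2 had a tested row and neither passed: miR-21a-5p at -0.02 (SE 0.172) and miR-137-3p at 0.28 (SE 0.23). No blood or vascular miRNA was tested. Adjusted over the list alone, 0 members of any miRNA list passed.

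**Figure D4:**
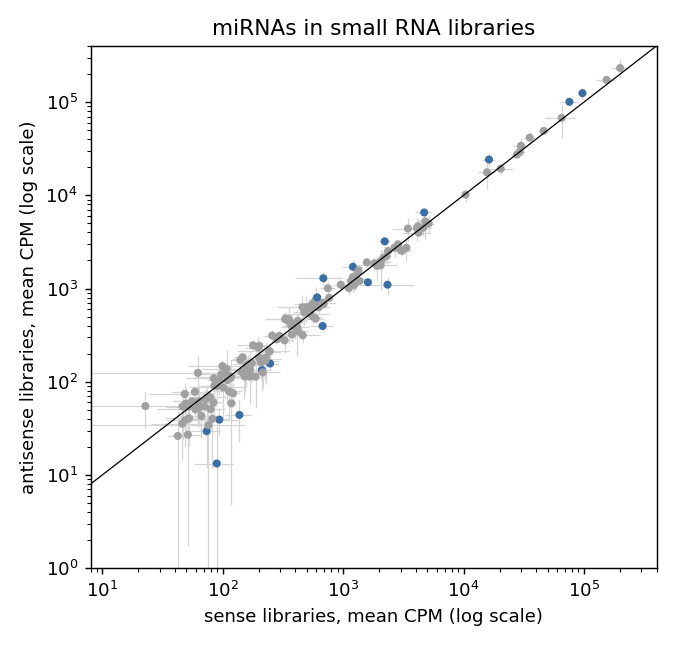
Mean CPM of miRNAs in the antisense libraries (y axis, log scale) against the sense libraries (x axis, log scale), with 1 SD over 3 libraries as grey bars, whose lower ends run off the axis where they reach 0. Each point is 1 of 158 tested miRNAs, blue points have an unadjusted p under 0.05 (18 miRNAs), and the line marks equal means.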

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

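The test on all rows of the small RNA table was among the alternatives fixed at the start, and the 4 transcripts named here were chosen after their values were seen. The small RNA table also holds rows that are transcript identifiers, which the miRNA comparison did not use. When all rows were tested together, 7 of 8129 tested transcripts were higher and 9 were lower in antisense, and none of 159 miRNAs passed. The files do not pair these identifiers with gene names. ENSMUST00000167688.2 was 189-fold higher in antisense, at 1223 ± 302 against 6.47 ± 3.29 CPM (SD, n = 3), and ENSMUST00000159663.8 was at least 2810-fold higher, at 699 ± 183 CPM against 0. ENSMUST00000135267.8 was 5440-fold lower, at 2.13 ± 0.44 against 11580 ± 947 CPM, and ENSMUST00000134947.8 was at least 4150-fold lower, at 0 against 1109 ± 189 CPM. Lower bounds use a floor of 3 counts over the group. These transcripts are given because they lie outside the miRNA comparison and differ widely between the groups. No explanation was tested for them.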

How the results depend on the processing

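Gas5 left out of the totals, and the settings on overlapping genes, were chosen after the data were seen; the other alternatives were not. Gas5 in total RNA kept its direction and passed in every setting that held it, from -3.08 to -1.96, and from -3.08 to -2.37 with 1 library left out. On library totals alone 12804 genes were higher and 62 lower, with a median log2 fold change of 0.70. Outside Gas5 the antisense libraries held 5148971 to 5399527 counts and the sense libraries 4092306 to 4469297. TMM-effective sizes were also larger in antisense (7464277 to 7786867) than in sense (5838607 to 6417995). Thus TMM ranked the groups in size as counts outside Gas5 did. Gas5 took a mean 45.3% of sense and 11.6% of antisense counts. On library totals this lowers the shares of all other genes more in sense, so signs there are not free of Gas5. The following genes, negative on the TMM scale, were then positive, none passing: Snhg20 0.17, Tug1 0.34, Miat 0.46, Oip5os1 0.41, Rmrp 0.21, Bsn 0.026, Pclo 0.28, Camk2a 0.24, Nlgn3 0.39, Nptx1 0.23, Reln 0.20, Map1a 0.074, Map1b 0.14, Kif5a 0.15, Jund 0.15, Nr4a3 0.38, Mt1 0.32, Mt2 0.27, Per1 0.38, Cox4i1 0.32, Atp5b 0.37, Rps18 0.35, Rpl13 0.37, Eif4g1 0.33, Eef2 0.31, Drosha 0.34, Elavl3 0.31, H4c9 0.49, H2bc4 0.49, Atp1b2 0.26, Aldh1l1 0.27, Slc4a4 0.43, Mbp 0.39, Cspg4 0.42, Fn1 0.40, Col4a1 0.41, Camk2b 0.41, Nr3c1 0.43, mt-Nd1 0.26, Dcp2 0.40 and Puf60 0.39. A minimum count of 50 tested fewer genes (13102) and gave 1795 higher and 402 lower genes and 6 lists (presynaptic, postsynaptic, cytoskeleton, RNA granule, astrocyte and vascular). Median-of-ratios factors, DESeq2, limma-voom, no filter and Gas5 left out of the totals gave 3316 to 5027 higher and 648 to 1026 lower genes. Genes overlapping no other gene, which are fewer (10494), gave 945 higher and 349 lower genes and 3 lists (presynaptic, postsynaptic and RNA granule), and the same 3 lists passed among protein-coding genes overlapping no other gene. Among named genes that passed, the call was lost with the direction kept for 19 genes in DESeq2, 19 at a minimum count of 50, 12 with a replicate block, 9 with Gas5 left out, 9 among genes overlapping no other gene, 5 in limma-voom, 4 with no filter, 3 with median-of-ratios factors and 4 on library totals alone, apart from those listed as positive there. Fewer named genes were tested at a minimum count of 50 and among genes overlapping no other gene, so those losses came from smaller sets. With an estimated correlation 0 lists passed. Leaving out 1 library gave 3392 to 3987 higher genes, 492 to 1100 lower genes and 7 to 15 lists.

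In small RNA no filter gave 1 higher miRNA (miR-1247-5p) and 5 lower (miR-138-5p, miR-148a-3p, miR-328-3p, miR-365-3p and miR-375-5p), and all rows together gave 7 higher and 9 lower rows, all transcripts. Leaving out 1 library gave 0 higher and 0 to 2 lower miRNAs and 0 to 1 lists. Several miRNAs that did not pass changed sign. miR-30d-5p stood at -0.00301 with median-of-ratios factors, -0.16 on library totals alone, -0.00299 in DESeq2, -0.0701 in limma-voom, -0.00802 with no filter, -0.0880 with a minimum count of 50, -0.00451 with a replicate block and -0.15 over all rows of the table. miR-9-5p stood at -0.0122 on library totals alone. miR-9-3p stood at -0.17 on library totals alone, -0.0103 in limma-voom, -0.0776 with a minimum count of 50 and -0.14 over all rows of the table. miR-382-5p stood at -0.0392 on library totals alone. miR-125b-5p stood at 0.0103 in limma-voom. With 1 library left out the ranges were -0.13 to 0.0697 for miR-125b-5p, -0.0673 to 0.0542 for miR-21a-5p, -0.27 to 0.0428 for miR-27b-3p, -0.0587 to 0.00827 for miR-30c-5p, -0.15 to 0.13 for miR-30d-5p, -0.28 to 0.0463 for miR-379-5p and -0.0559 to 0.0602 for miR-9-3p. The cause was not tested where none is given. Libraries with the same replicate number did not vary together: the correlations of their deviations were 0.0512, -0.0585 and -0.00933 in total RNA and -0.0413, -0.215 and 0.027 in small RNA. With a replicate block 3428 genes were higher and 695 lower, Gas5 in total RNA stood at -2.68, 13 lists passed, oligodendrocyte markers in addition to the other 12, and 0 miRNAs and 0 miRNA lists did. Depth limits miRNAs of low count, since 193501 to 258237 counts covered all miRNAs of a library.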

Other observations

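The thinning of libraries was set out before its value was seen; the splits of the libraries and the overlap, receptor family, Gas5 share, Gas5-free and matched-list tests were chosen only after the results were seen. Of 160 tested genes whose names end in os, with or without a number after it, 95 were higher in antisense and 5 lower in edgeR. That ending marks genes lying opposite another gene, but the match was by spelling alone and can take in other genes. Of 3549 long noncoding RNA genes 1620 were higher, a difference that was not tested. Chemoreceptor genes were over-represented in both directions: of 424 odorant receptor genes (Olfr), 100 were higher (23.6% against 18.1% of other genes) and 36 lower (8.49% against 4.26%), and of 182 vomeronasal receptor genes (Vmn), 57 were higher (31.3% against 18.1%) and 16 lower (8.79% against 4.31%). Two-sided Fisher's exact tests over these 4 comparisons gave Benjamini-Hochberg p of 7.16e-05 to 0.00881. Both families have many similar copies, so their counts are uncertain, and genes are not independent replicates. The tests did not match genes on abundance, so they do not show an effect of the family itself.

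Mitochondrial tRNA genes had low counts, most of them in the antisense libraries. No tRNA gene had more than 5 counts over the sense libraries, so the filter could pass one only through its antisense counts. The 2 that reached the test could therefore only lie higher, and both passed in edgeR. mt-Tc was at least 10.3-fold higher, with 38 counts against 0. mt-Ty had 86 counts against 1, a scaled ratio of 69.9 (95% exact interval 12.2 to 2790). Over all tRNA genes of the table, tested or not, the 8 of the light strand by textbook assignment summed to 205 antisense and 6 sense counts, and the 14 of the heavy strand to 80 and 12, with mt-Tl2 at 35 and 1. mt-Nd6, the light-strand mRNA, was higher (log2 fold change 1.19, SE 0.235).

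The first pattern is the large set of genes near 0 in sense libraries and counted in antisense libraries. Genomic DNA in the antisense libraries would reach silent genes wherever they lie. Of 14091 genes with at most 10 sense counts that overlap no other gene, 0.887% reached 60 antisense counts, against 17.1% of 2567 such genes that overlap an expressed gene. This argues against genomic DNA as the main source of the excess in overlapping genes. A smaller amount is not excluded, since gene length was not matched and 125 genes overlapping none reached 60. A deeper antisense group is argued against because 3485 genes were higher after thinning to 4307886 counts outside Gas5. Without Gas5 in the totals 3519 genes were higher, but the TMM factors of the main fit already offset most of its load. That count therefore cannot decide on the load of Gas5. Insofar as Gas5 lowered the depth of other genes in sense, the thinning covers it and argues against it as the main source. Reads of an overlapping expressed gene may account for part of the pattern, with an odds ratio of 23.1 (95% interval 18.8 to 28.6), but of 1776 genes over 4-fold higher 278 overlap no other gene, 111 overlap only genes of low count and 652 have no position, and these are left open, as is an effect of the capture itself. Of the 10 splits of the 6 libraries the real one gave 4531 calls and the highest other 0, so 1 split, the real one, gave as many; 10 splits are too few for a share under 0.05.

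The second pattern is Gas5 itself, higher in the libraries named sense. One library under the wrong label is argued against, because the lowest sense share, 32.66%, lies above the highest antisense share, 14.2%. Bait RNA sequenced with the sample, captured cellular Gas5 and a swap of both whole groups cannot be told apart. Each could leave Gas5 higher in the libraries named sense, and sums per gene hold no part of Gas5 that separates them. The size of the ratio of 3.91 between mean shares was not modelled for any of them.

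The third pattern is the lean of 12 lists toward lower values, a call that none of them keeps with an estimated correlation. Among protein-coding genes overlapping no other gene, the median log2 fold change was 0.11 in the fifth with the lowest abundance and -0.14 in the fifth with the highest, so part of the lean may be a shift shared by genes of like abundance. Against 10000 random lists of such genes matched on abundance, 7 of the 12 medians lay below 95% of the random ones, and 6 did so also with only their own members of that kind: presynaptic (-0.30 against -0.12), cytoskeletal, GABAergic, glucocorticoid-responsive, astrocyte and vascular genes. For these 6 the shift alone rarely gave medians as low. The lists were picked as lower in the same data, so the comparison does not decide whether the shift is the whole cause. Random lists ignore correlation between genes. Camera among protein-coding genes overlapping no other gene gave adjusted p-values of 0.0107 for presynaptic, 0.0621 for cytoskeletal, 0.297 for GABAergic, 0.108 for glucocorticoid-responsive, 0.0763 for astrocyte and 0.186 for vascular genes. For the 5 within the range of the random lists (neuronal long noncoding RNAs, activity-regulated, ribosomal protein, translation factor and RNA granule genes) the shift cannot be told apart from a change of the list, postsynaptic and activity-regulated genes lay below by 1 of the 2 ways and stay open, and a difference in what the capture retained was not tested.

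For small RNA each of the 10 splits gave 0 miRNAs, as did the real one, and 10 splits are too few for a share under 0.05.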
